A study of Mus musculus with 18 samples.

How the data were processed

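RNA from 18 mouse kidney samples was measured on an Affymetrix array with 45101 probe sets, 1 array per sample. The samples fell into 3 groups of 6, taken from the labels: renal cell carcinoma of exposed mice (carcinoma), non-tumour kidney of exposed mice (treated kidney, for which the labels also use the word hyperplasia) and kidney of vehicle control mice (control kidney). Per the labels' protocols, B6C3F1 mice inhaled vinylidene chloride, a chlorinated compound used to make plastics, at 0, 6.25, 12.5 or 25 ppm on 5 days a week for 2 years. The dose and the sex of the mouse behind each sample, and whether a treated kidney and a carcinoma came from the same mouse, are not given in the sources used here. The series title names male mice, whereas the treatment protocol names both sexes. The extraction protocol on the labels describes liver, so how RNA was taken from these kidneys is not given in the sources used here.

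The deposited table held 1 linear signal intensity per probe set and array. The authors used MAS5, per the submitters' processing notes, and no version or settings are stated there. The arrays shared 1 scale: the mean intensity left after trimming 2% of the values at each end was 500.003 on each of the 18 deposited columns. Biotin-labelled RNA was made with a 3' amplification kit, per the labels' protocols. Array data carry no counting depth, and the number of arrays limits the precision. The median intensity of the arrays lay between 86.5 and 108.

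Probe sets were named from the annotation supplied with the platform. Of the 45101 probe sets, 64 were spiked or control features, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none. The probe sets with 1 symbol covered 18193 symbols. A mouse gene table of assembly GRCm38.p6 held the gene identifier of 34741 probe sets, and 0 symbols had to be updated. No coordinates were used. No probe set, with 1 symbol or several, was annotated to Trp53, the gene named in the series title, so Trp53 itself was not analysed here.

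Intensities were transformed as log2(intensity + 16). The array medians on that scale differed by up to 0.28, above the limit of 0.25 set beforehand, so the arrays were quantile normalized. After this step the median of each array was 6.85, an intensity of 99.7. A probe set was kept if it lay above its array's median on at least 6 arrays, which left 20630 probe sets with 1 symbol. Each gene was represented by its kept probe set with the highest mean over the 18 arrays, which gave 11813 genes. A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a trend of variance on mean). P values were adjusted by the Benjamini-Hochberg method over the 11813 genes of a comparison, and genes with an adjusted p under 0.05 were called. All p values are two-sided. Where all 6 arrays of the lower group lay below the array median, no fold change is given, only the lowest fold that the array median allows, as "at least".

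Gene lists were tested with limma's camera with an inter-gene correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. There were 24 pathway lists, covering stress responses, DNA damage, growth, metabolism, immunity and matrix, and 21 marker lists for nephron segments, for other cells of the kidney and for tissues that a piece could carry along. Of these 45 lists, the 40 with at least 3 tested genes were tested. The lists, the comparisons, the tests, the processing choices and the alternatives were fixed before the data were examined, apart from those named as later additions. The rule for naming genes was fixed with them: the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, then for each list up to 4 called members with the largest change, or the 2 with the smallest p if none was called, and Mdm2 in each comparison. Examples were chosen from that set.

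Array quality was judged from the 3' to 5' differences of the Gapdh and Actb control probe sets, compared between groups by exact permutation tests adjusted over 12 tests, and from principal components of the 11813 genes. Changes that shared a group of arrays were compared with 100 simulated draws of unchanged groups and with the shared arrays divided at random, 3 arrays to each side. Each comparison was tested on simulated data with 200 of the 11813 genes changed. With the same spread in each group, 23 of 67 genes changed by 0.5 (log2), 52 of 67 changed by 1 and 63 of 66 changed by 2 were recovered for carcinoma against control kidney, with 4 of 11613 unchanged genes called. The treated against control comparison recovered 24, 52 and 61 genes of these sizes with 4 unchanged genes called, and the carcinoma against treated comparison recovered 34, 51 and 63 with 9. When each group kept its own, unequal spread, the unchanged genes called were 28.2% of the calls for carcinoma against control (55 genes), 25.3% for carcinoma against treated (48 genes) and 4.26% for treated against control (6 genes). These shares belong to 200 changed genes. They do not carry over to the measured carcinoma comparisons, where far more genes were called.

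The alternatives set beforehand were centring of each array on its median, a smaller and a larger pseudocount, no filter and a stricter filter on dim probe sets, other ways to combine the probe sets of a gene, no variance trend, weights per array, the 12 arrays of a comparison alone, a 2-fold minimum, the 3' to 5' mean as a covariate, the replicate number as a block, and each array left out in turn. Quantile normalization, planned as an alternative, became the main choice. Added after the data were seen were the values as scaled by the authors, fits without the control arrays 5 and 6, fits without the carcinoma arrays 3 and 5, 1 weight per group, the treated and control arrays alone without the control arrays 5 and 6, and for the lists also centred arrays and each array left out in turn. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The 10092 probe sets with no symbol or several symbols were left out of the gene tests.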

Results

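Gene expression was measured in 18 kidney samples of B6C3F1 mice from a 2-year inhalation study of vinylidene chloride, with 6 arrays each for carcinoma, treated kidney and control kidney. Values below are log2 fold changes with their standard error unless another unit is given, each from 6 arrays per group, and adjusted p values are those of limma. The first principal component held 63.3% of the variance and set the carcinomas apart from both kidney groups. The second held 13.6% and set the carcinoma arrays 3 and 5 apart: their correlation with the control mean across genes, which are not independent replicates, was 0.86 in both, against 0.75 to 0.78 in the other 4 carcinomas. The control arrays 5 and 6 carried high Xist, the transcript of the inactive X chromosome, with little signal from the Y-linked gene Eif2s3y, as the plot of both transcripts shows. The 3' to 5' difference of Actb, a sign of RNA quality and labelling, was 0.617 ± 0.068 in carcinoma and 0.858 ± 0.073 in control kidney (log2, SD, n = 6, exact permutation p = 0.00216, adjusted p = 0.0260). That of Gapdh was −0.502 ± 0.106 in carcinoma and −0.523 ± 0.050 in control kidney (exact permutation p = 0.675, adjusted p = 0.779, n = 6).

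**Figure D1:**
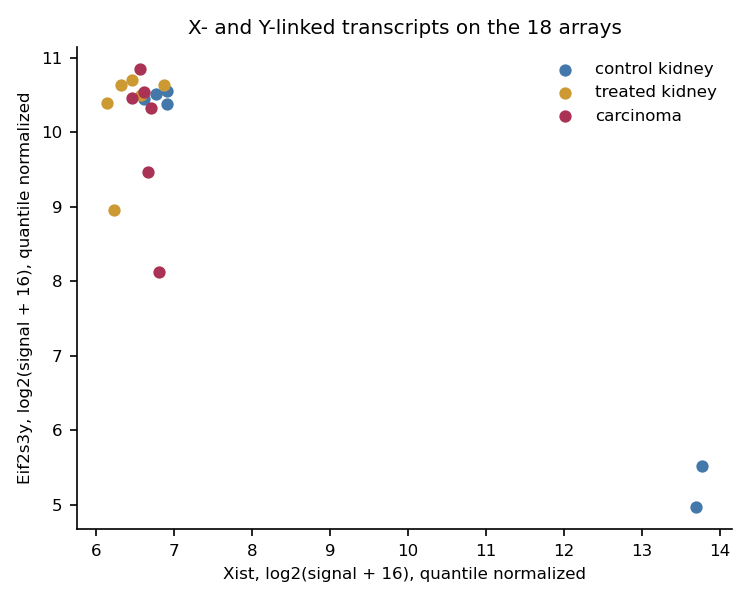
Xist and Eif2s3y on the 18 arrays, each axis a quantile normalized log2 signal after adding 16 to the intensity, 1 point per array. The control arrays 5 and 6 lie at Xist 13.69 and 13.77 with Eif2s3y at 4.97 and 5.52, and carcinoma 2, carcinoma 5 and treated kidney 4 have Eif2s3y at 8.12, 9.46 and 8.95 with low Xist.

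The first comparison asked how the carcinomas differed from kidney of vehicle control mice. Genes of macrophages, injured tubules and dividing cells were higher in the carcinomas, and genes of every nephron segment tested were lower. Of the lists behind these statements the collecting duct list alone kept its call with an estimated correlation between genes (adjusted p = 0.00579, the others 0.0643 to 0.343). Gpnmb, a membrane glycoprotein of macrophages and lysosomes, was at least 32.8-fold higher (adjusted p = 8.17e-07), and Lcn2, an iron-carrier protein of injured tubules, rose by 4.76 ± 0.71 (adjusted p = 3.44e-05). Egf, the growth factor made by the thick ascending limb, fell by 6.89 ± 0.18 (adjusted p = 2.26e-14), from a mean log2 signal of 14.29 ± 0.19 to 7.40 ± 0.53 (SD, n = 6). Calb1, a calcium-binding protein of the distal tubule, was at least 62.7-fold lower (adjusted p = 5.81e-14), and Slc12a3, its sodium chloride transporter, at least 45.8-fold lower (adjusted p = 2.43e-12). Of 11813 genes, 6069 (51.4%) were called, 3020 up and 3049 down. The 6 arrays of each group did not overlap in 2773 called genes, where chance gives 0.216% of genes.

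**Figure D2:**
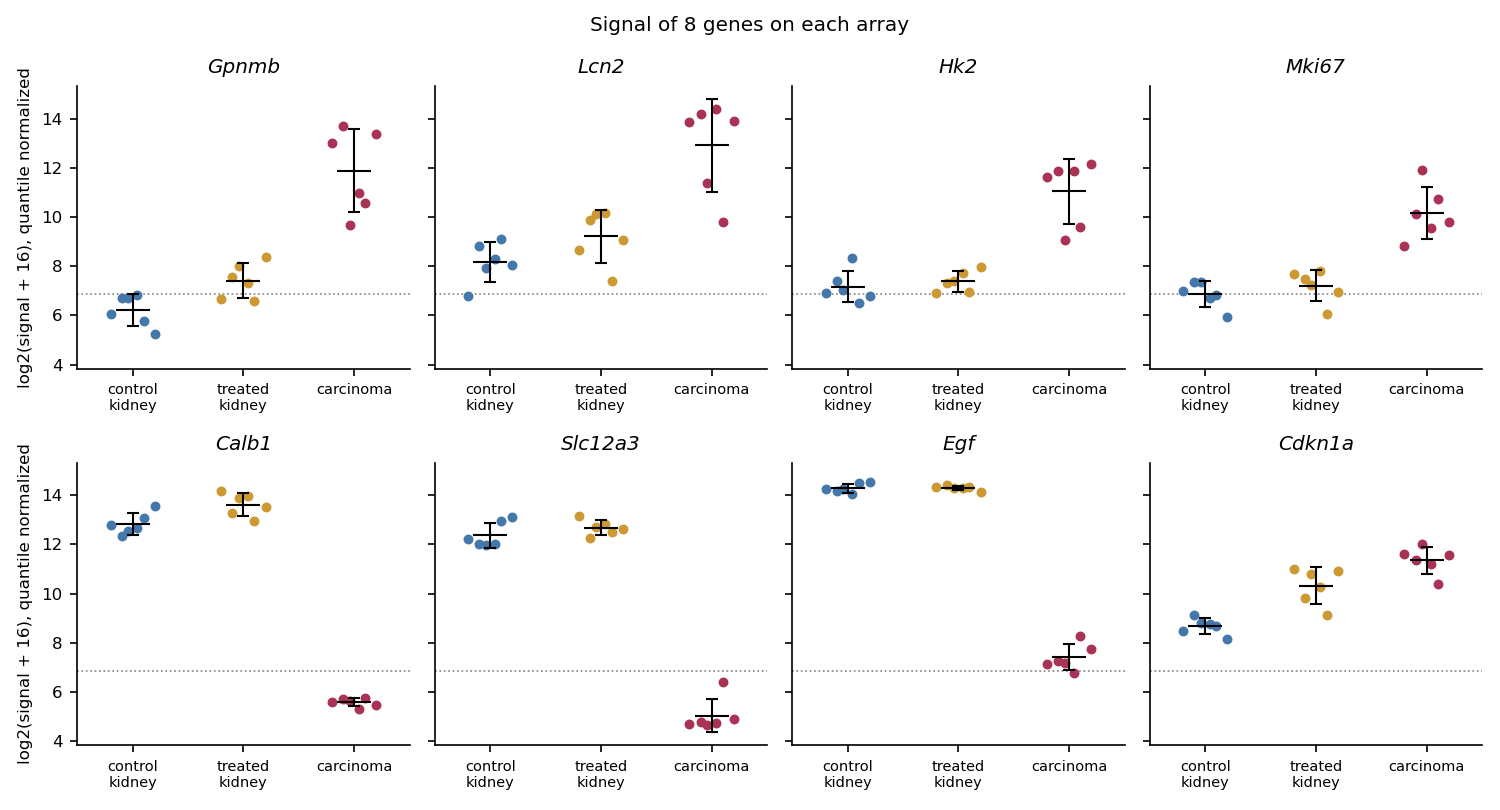
Normalized log2 signal of 8 genes on each array, by group, with bars at the mean ± SD of 6 arrays and a dotted line at the array median of 6.85. Egf and Calb1 separate the carcinomas from both kidney groups, whereas Cdkn1a has means of 8.67 in control kidney, 10.33 in treated kidney and 11.36 in carcinoma.

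The other largest rises included Cd68, a macrophage lysosomal protein (3.98 ± 0.38), Hk2, a hexokinase at the entry to glycolysis (3.88 ± 0.48), Aldh1l2, a mitochondrial folate enzyme (3.89 ± 0.42), Vgll3, a transcription cofactor (4.07 ± 0.46), and the interferon-inducible Ifi207 (3.99 ± 0.47). The keratin Krt20 was at least 17.9-fold higher, the annexin Anxa8 at least 12.8-fold, Ahnak2 at least 6.72-fold, the actin cross-linker Actn3 at least 5.90-fold and the macrophage lectin Chil3 at least 5.06-fold. Among the largest falls were those of the kallikrein Klk1 (−6.99 ± 0.49), the vitamin D-dependent calcium-binding protein S100g (−6.53 ± 0.55), the potassium channel Kcnj1 (−6.47 ± 0.39), the loop transporter Slc12a1 (−6.47 ± 0.61), the nuclease Dnase1 (−6.54 ± 0.48), the histidine decarboxylase Hdc (−6.46 ± 0.55) and the anion transporter gene Slc22a22 (−6.57 ± 0.71). The anion transporter genes Slc22a8 and Slc22a7 were at least 49.0-fold and at least 31.6-fold lower.

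Markers of the nephron fell in each segment. In the early proximal tubule list 16 of 18 genes fell and 0 rose (1 up and 16 down when adjusted over the list alone, camera adjusted p = 8.66e-08, and adjusted p = 0.133 with an estimated correlation). The glucose transporter Slc5a2 fell by 6.22 ± 0.24 and the phosphate transporter Slc34a1 by 5.73 ± 0.55. All 8 genes of the S3 proximal segment fell, among them the amino acid transporter gene Slc7a13 at −6.35 ± 1.22 (camera adjusted p = 0.000661, and adjusted p = 0.133 with an estimated correlation). In the thick ascending limb list 6 of 7 genes fell (7 when adjusted over the list alone, camera adjusted p = 5.47e-06, and adjusted p = 0.120 with an estimated correlation). Uromodulin, Umod, fell by 5.92 ± 0.80. In the distal convoluted tubule list 3 of 4 genes fell, with a median of −5.43, or −4.57 with dim genes at their bound (camera adjusted p = 0.00214, and adjusted p = 0.133 with an estimated correlation). All 9 collecting duct principal cell genes fell, with a median of −3.98, or −2.41 with dim genes at their bound, and this call held with an estimated correlation (camera adjusted p = 9.85e-09, and adjusted p = 0.00579 with an estimated correlation). The water channel genes Aqp4 and Aqp3 were at least 17.3-fold and 13.7-fold lower. In the intercalated cell list 7 of 8 genes fell, with a median of −3.30, or −2.49 with dim genes at their bound (camera adjusted p = 1.69e-07, and adjusted p = 0.0643 with an estimated correlation). The anion exchanger Slc26a4 was at least 13.7-fold lower and the channel gene Aqp6 at least 11.5-fold lower.

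Podocyte and endothelial markers also fell as groups. In the podocyte list 5 of 7 genes fell and 1 rose (2 rose when adjusted over the list alone, camera adjusted p = 0.0148, and adjusted p = 0.157 with an estimated correlation). Podxl, a surface protein of podocytes, fell by 2.48 ± 0.17 and nephrin, Nphs1, was at least 2.17-fold lower. Endothelial genes fell in 11 of 14 cases (camera adjusted p = 3.69e-06, and adjusted p = 0.133 with an estimated correlation). The receptor gene Tek fell by 1.45 ± 0.15 and Flt1 by 1.42 ± 0.14. Of 12 fibroblast and pericyte genes 4 rose and 1 fell (camera adjusted p = 0.651). The collagen gene Col1a1 rose by 1.57 ± 0.48 and the receptor gene Pdgfra fell by 1.32 ± 0.34.

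Genes of mitochondrial and tubular metabolism fell together. All 18 oxidative phosphorylation genes fell, with a median of −0.46 (camera adjusted p = 3.65e-09, and adjusted p = 0.0643 with an estimated correlation). Uqcrfs1 of complex III fell by 1.14 ± 0.15 and Sdha of complex II by 1.04 ± 0.14. Of 15 TCA cycle genes 13 fell (14 when adjusted over the list alone, camera adjusted p = 9.93e-07, and adjusted p = 0.133 with an estimated correlation). Dlst fell by 1.38 ± 0.26. Of 20 fatty acid oxidation genes 13 fell (camera adjusted p = 0.000107, and adjusted p = 0.133 with an estimated correlation). Cpt2 fell by 1.61 ± 0.27, Ehhadh by 1.60 ± 0.20 and the coactivator gene Ppargc1a by 1.43 ± 0.19. All 4 gluconeogenesis genes fell (camera adjusted p = 0.0148, and adjusted p = 0.301 with an estimated correlation). Pck1 fell by 4.57 ± 0.32 and Pcx by 2.39 ± 0.62. Glycolysis genes went both ways, 4 up and 3 down of 13 (camera adjusted p = 0.484). Hk2 rose by 3.88 ± 0.48, Pfkp by 1.57 ± 0.22 and Pkm by 1.26 ± 0.34. In the cholesterol synthesis list 2 of 12 genes rose and 3 fell (camera adjusted p = 0.400). Cyp51 fell by 2.93 ± 0.34 and Idi1 by 2.07 ± 0.40. Of 23 genes of xenobiotic and mercapturate metabolism 16 fell and 1 rose (camera adjusted p = 0.00132, and adjusted p = 0.343 with an estimated correlation). The mean difference of that list from control was −0.39 in carcinoma 3 and −0.34 in carcinoma 5, against −3.32 to −2.71 in the other 4 carcinomas. Ces1d fell by 5.41 ± 1.36 and Cyp2e1 fell by 5.24 ± 1.26. Of 13 androgen-dependent kidney genes 9 fell and 1 rose (camera adjusted p = 0.0224, and adjusted p = 0.510 with an estimated correlation). Kap fell by 5.93 ± 1.04. The control arrays 5 and 6 had a mean of −2.08 and −2.17 on that list, against 0.99 to 1.15 in the other 4 controls.

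Oxidative stress and TP53, named in the series title, were represented by several lists. Of 22 NRF2 targets, genes switched on by an oxidant-sensing factor, 9 rose and 4 fell (camera adjusted p = 0.315). The epoxide hydrolase Ephx1 rose by 2.08 ± 0.28, Cbr3 rose by 1.33 ± 0.41, Aox1 was at least 2.58-fold higher and the malic enzyme Me1 fell by 1.72 ± 0.33. Of 18 antioxidant enzymes and metallothioneins 8 fell and 2 rose (9 and 2 when adjusted over the list alone, camera adjusted p = 0.0420, and adjusted p = 0.510 with an estimated correlation). Sod3 fell by 1.54 ± 0.37, Msra by 1.17 ± 0.29, Txnrd2 by 0.81 ± 0.22 and Sod2 by 0.77 ± 0.20. Of 24 p53 target genes 14 rose and 1 fell (camera adjusted p = 0.00206, and adjusted p = 0.134 with an estimated correlation). Pmaip1 rose by 2.82 ± 0.26, the cell cycle inhibitor Cdkn1a by 2.69 ± 0.31, Apaf1 by 1.82 ± 0.15 and the receptor gene Eda2r was at least 5.35-fold higher. Mdm2, whose product limits p53, rose by 0.33 ± 0.11 (adjusted p = 0.0235). That call was lost without carcinoma 1 (adjusted p = 0.0594) or carcinoma 6 (adjusted p = 0.0563). It was also lost without the control arrays 5 and 6 (0.28, adjusted p = 0.0995) and with the mean over the kept probe sets (0.16, adjusted p = 0.238), and the direction turned with the most variable probe set (−0.01, adjusted p = 0.964). Of 17 DNA repair genes 13 rose (15 when adjusted over the list alone, camera adjusted p = 9.63e-05, and adjusted p = 0.133 with an estimated correlation). The checkpoint kinase Chek1 rose by 1.78 ± 0.20 and Brca1 was at least 2.76-fold higher. Of 24 proliferation genes 23 rose and 1 fell, with a median of 1.99, or 1.55 with dim genes at their bound (camera adjusted p = 2.10e-09, and adjusted p = 0.134 with an estimated correlation). Mki67, present in cycling cells, rose by 3.29 ± 0.42, the nucleotide reductase Rrm2 by 2.82 ± 0.28, and the mitotic kinase Cdk1 was at least 7.67-fold higher.

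Further stress and growth lists gave mixed results. Of 20 hypoxia targets 10 rose and 2 fell (11 and 2 when adjusted over the list alone, camera adjusted p = 0.0148, and adjusted p = 0.216 with an estimated correlation). The lipid droplet protein Plin2 rose by 1.56 ± 0.21, the peptide Adm rose by 1.04 ± 0.27, Ankrd37 was at least 6.48-fold higher and the glucose transporter Slc2a1 fell by 0.88 ± 0.22. Of 14 genes of the unfolded protein response 7 rose and 1 fell (camera adjusted p = 0.0446, and adjusted p = 0.343 with an estimated correlation). Trib3 rose by 2.61 ± 0.41, Asns by 1.92 ± 0.38 and Ddit3 by 1.80 ± 0.20. Of 15 immediate early and heat shock genes 8 rose and 2 fell (9 and 2 when adjusted over the list alone, camera adjusted p = 0.0725). The small heat shock protein Hspb1 rose by 1.88 ± 0.41 and the phosphatase Dusp1 fell by 1.42 ± 0.46. Of 18 growth factor signalling genes and oncogenes 7 rose and 6 fell (8 and 6 when adjusted over the list alone, camera adjusted p = 0.820). Myc rose by 3.22 ± 0.31, the receptor gene Axl rose by 2.16 ± 0.40, Fgfr1 fell by 1.41 ± 0.25 and Kit fell by 1.35 ± 0.30. Of 11 renal cancer tumour suppressors 3 rose and 3 fell (camera adjusted p = 0.702). Cdkn1c fell by 3.32 ± 0.34 and fumarase, Fh1, by 0.78 ± 0.07. Of 14 apoptosis regulators 8 rose and 4 fell (camera adjusted p = 0.246). The pro-apoptotic Bcl2l11 rose by 1.17 ± 0.20.

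Injury, matrix and immune genes were tested as separate lists. Of 22 genes of tubular injury and dedifferentiation 15 rose and 2 fell (camera adjusted p = 7.44e-05, and adjusted p = 0.343 with an estimated correlation). The mean of that list above control was 0.34 in carcinoma 3 and 0.46 in carcinoma 5, against 2.08 to 2.89 in the other 4. The adhesion receptor Cd44 rose by 3.63 ± 0.55, S100a6 by 2.81 ± 0.39 and Lcn2 by 4.76 ± 0.71. Of 22 matrix and fibrosis genes 9 rose (camera adjusted p = 0.0344, and adjusted p = 0.517 with an estimated correlation). The protease inhibitor Timp1 rose by 2.58 ± 0.31, Sparc by 2.06 ± 0.22 and periostin, Postn, by 1.83 ± 0.57. Of 15 macrophage markers 14 rose (camera adjusted p = 2.31e-08, and adjusted p = 0.134 with an estimated correlation). The endotoxin co-receptor Cd14 rose by 3.03 ± 0.63 and the complement component C1qb by 2.31 ± 0.23. Of 3 neutrophil markers S100a9 (3.23 ± 0.87) and S100a8 (2.99 ± 0.83) rose (camera adjusted p = 0.186), and the list mean above control was 6.88 in carcinoma 3 and 4.05 in carcinoma 5 against 0.28 to 2.33 in the other 4. Of 16 interferon response genes 10 rose (camera adjusted p = 0.00356, and adjusted p = 0.408 with an estimated correlation). Ifit2 rose by 1.86 ± 0.21 and the immunoproteasome subunit Psmb8 by 1.62 ± 0.29. Of 6 genes of MHC class II presentation 5 rose (camera adjusted p = 0.0222, and adjusted p = 0.404 with an estimated correlation). The invariant chain Cd74 rose by 1.42 ± 0.29 and H2-Ab1 by 1.02 ± 0.24. Of 6 complement genes 3 rose and 1 fell (camera adjusted p = 0.449). C1ra rose by 2.30 ± 0.49, C2 rose by 1.85 ± 0.19 and Cfi fell by 2.05 ± 0.26. Of 5 B and plasma cell genes 1 fell, the antibody joining chain Jchain (−2.50 ± 0.84, adjusted p = 0.0197, camera adjusted p = 0.489). The Jchain call was lost without carcinoma 1 (adjusted p = 0.0527) or carcinoma 2 (adjusted p = 0.0522).

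Markers of other tissues gave few calls. Of 5 adipocyte genes 0 were called (camera adjusted p = 0.848), with Car3 at −3.19 ± 1.34 (adjusted p = 0.0547). Car3 passed without carcinoma 3 (−3.76, adjusted p = 0.0264), carcinoma 5 (−4.43, adjusted p = 0.00141), both (−5.47, adjusted p = 1.84e-05) or control 5 (−3.52, adjusted p = 0.0496). It also passed with a pseudocount of 1 (−3.66, adjusted p = 0.0459) and with weights per array (−4.76, adjusted p = 0.000512). Of 6 hepatocyte genes 3 fell and 1 rose (camera adjusted p = 0.315). Albumin, Alb, fell by 3.77 ± 0.60 and Apoa2 by 2.12 ± 0.28. Of 6 urothelial genes 3 fell (camera adjusted p = 0.178). The keratin Krt7 fell by 3.93 ± 0.48 and Upk3a by 1.43 ± 0.45. The 3 tested sex-linked genes gave 0 calls (camera adjusted p = 0.449). The Y-linked gene Uty lay at 1.43 ± 0.86 and Kdm5d at 1.26 ± 0.79. These differences rest on the control arrays 5 and 6, with Uty at a log2 signal of 4.37 and 5.30. It was 9.62 to 9.85 in the other control arrays and 8.02 to 10.25 in the carcinomas. The lists with fewer than 3 tested genes were not tested as groups. In them the muscle light chain gene Mylpf rose by 1.00 ± 0.31 (adjusted p = 0.0115), 1 of 2 tested skeletal muscle genes. The T and NK cell genes Nkg7 (−0.26 ± 0.31, adjusted p = 0.508) and Cd8a (−0.14 ± 0.36, adjusted p = 0.760), the erythroid gene Alas2 (−0.01 ± 0.53, adjusted p = 0.985) and the lung gene Sftpb (0.05 ± 0.16, adjusted p = 0.825) did not pass, nor did the 2 tested adrenal cortex genes. Without the carcinoma arrays 3 and 5, Nkg7 (−0.68, adjusted p = 0.0419) and Alas2 (−0.80, adjusted p = 0.0178) were called lower.

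**Figure D3:**
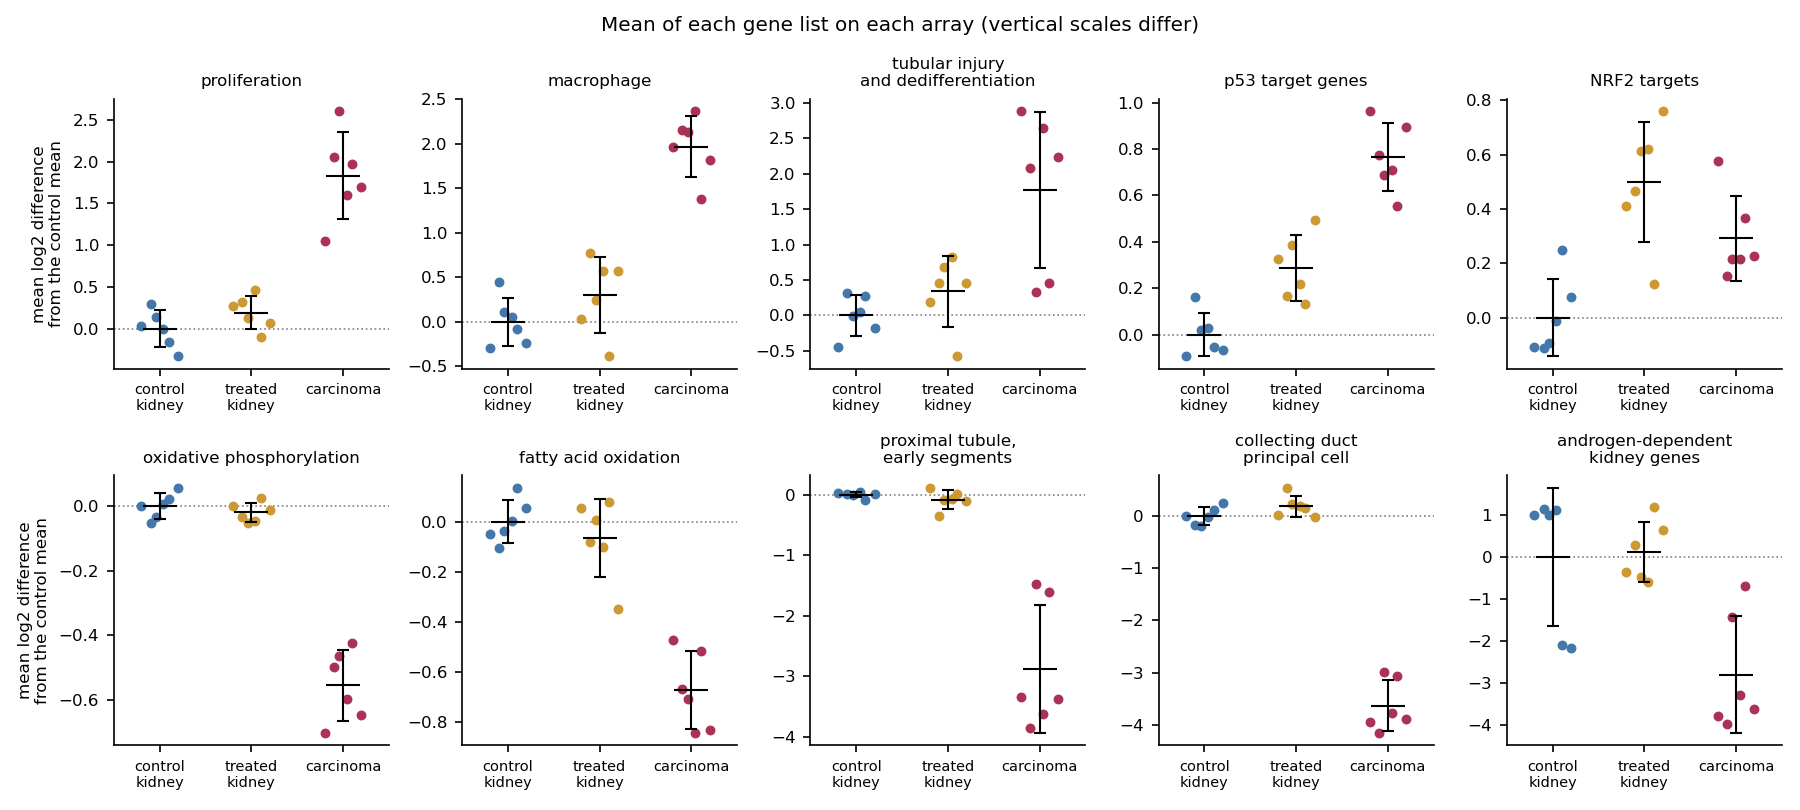
Mean log2 difference from the control mean over the genes of 10 lists on each array, by group, with bars at the mean ± SD of 6 arrays, a dotted line at 0 and vertical scales that differ between panels. On the early proximal tubule list the carcinoma arrays 3 and 5 lie at −1.48 and −1.61 and the other 4 carcinomas between −3.85 and −3.34.

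Of the 40 lists tested, 25 were called in carcinoma against control, 10 up and 15 down, and the collecting duct list was the 1 that kept its call with an estimated correlation. For lists without a second count above, the count adjusted over the list alone equalled that over all genes. The median, the mean and the test differed in sign for growth factor signalling, renal cancer tumour suppressors and adipocyte genes, none of them called. Without the carcinoma arrays 3 and 5, the calls ended for hypoxia (adjusted p = 0.114), matrix (0.651), MHC class II (0.144), the unfolded protein response (0.254) and podocytes (0.113), and without the control arrays 5 and 6 those of the antioxidant list (0.0584), Mdm2 and Mylpf (0.0517). These losses were not alike. Carcinoma 3 and 5 had matrix list means of 1.26 and 1.67 above control, against −0.06 to 0.76 in the other carcinomas. On the unfolded protein response list their means of 0.66 and 0.59 lay within the range of the others, 0.32 to 0.93. On the authors' scaling the call of the unfolded protein response ended (0.0868, and 0.0824 on centred arrays), and with weights per array that of Postn (0.0610). With the 3' to 5' mean as a covariate, the calls ended for matrix (0.353), MHC class II (0.102) and the unfolded protein response (0.121), as did those of 13 named genes, with the log2 change then in parentheses: Cbr3 (1.36), Mdm2 (0.21), Slc2a1 (−0.51), Postn (0.45), Kit (−1.05), Cd74 (0.96), H2-Ab1 (0.73), Dusp1 (−1.31), Col1a1 (0.82), Jchain (−2.67), S100a9 (2.89), S100a8 (2.66) and Mylpf (0.77). With 1 weight per group the calls of Cbr3, Mdm2, Postn and Upk3a ended while their log2 changes were as before (1.33, 0.33, 1.83 and −1.43).

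The second comparison set the carcinomas against non-tumour kidney of exposed mice. Gpnmb rose by 4.48 ± 0.60 (adjusted p = 1.37e-05), Cd44 by 4.06 ± 0.55, Hk2 by 3.66 ± 0.48 and Cd68 by 3.37 ± 0.38, the macrophage, adhesion and glycolysis genes described above. Calb1 was at least 109-fold lower (adjusted p = 1.10e-14), Slc12a3 at least 56.7-fold lower, and Egf fell by 6.90 ± 0.18 (adjusted p = 1.10e-14), from a mean log2 signal of 14.30 ± 0.09 to 7.40 ± 0.53 (SD, n = 6). Of 11813 genes 5719 (48.4%) were called, 2856 up and 2863 down, and in 2208 called genes the groups did not overlap, where chance gives 0.216% of genes. Of these calls, 2487 rises and 2607 falls were also called in the same direction against control kidney, 0 in opposite directions. Because both comparisons share the carcinoma arrays, their changes correlated in part by design: r across genes was 0.976, against a mean of 0.744 (−0.086 to 0.977) in simulated unchanged groups and 0.866 (0.773 to 0.929) when the carcinomas were divided between the comparisons.

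Other large rises were those of Ptgds, a prostaglandin D synthase (3.56 ± 0.51), Ifi207 (3.54 ± 0.47), Aldh1l2 (3.50 ± 0.42), Vgll3 (3.49 ± 0.46) and Ankrd37 (3.21 ± 0.41), with the ubiquitin ligase Rnf180 at least 9.06-fold, Ahnak2 at least 6.72-fold and Actn3 at least 5.90-fold higher. Large falls were those of Slc7a13 (−7.84 ± 1.22), S100g (−7.19 ± 0.55), Klk1 (−7.16 ± 0.49), Kcnj1 (−6.66 ± 0.39), Slc5a2 (−6.40 ± 0.24), Slc12a1 (−6.37 ± 0.61) and Slc22a22 (−6.36 ± 0.71), with the glycine-cleaving enzyme gene Gldc at least 27.3-fold and the transporter gene Abca13 at least 31.9-fold lower. Of 24 p53 target genes 9 rose and 1 fell, with Pmaip1 at 2.33 ± 0.26, Eda2r at 2.07 ± 0.28, Apaf1 at 2.01 ± 0.15 and Bbc3 at 1.08 ± 0.21 (camera adjusted p = 0.0489, and adjusted p = 0.341 with an estimated correlation), while Mdm2 lay at 0.09 ± 0.11 (adjusted p = 0.548). Of 22 NRF2 targets 3 rose and 6 fell (camera adjusted p = 0.301). Aox1 rose by 1.54 ± 0.31, Me1 fell by 1.39 ± 0.33, Nqo1 fell by 1.14 ± 0.26 and Gclm fell by 0.91 ± 0.14. Proliferation genes rose in 22 of 24 cases and fell in 1 (camera adjusted p = 1.21e-09, and adjusted p = 0.156 with an estimated correlation). Mki67 rose by 2.95 ± 0.42. Myc rose by 2.68 ± 0.31, the chemokine Ccl2 by 2.74 ± 0.55 and the early response factor Egr1 by 1.60 ± 0.50 (adjusted p = 0.0147), and Car3 fell by 4.27 ± 1.34 (adjusted p = 0.0140).

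In this comparison 24 lists were called, 9 up and 15 down. The 3 that kept their call with an estimated correlation were oxidative phosphorylation (18 of 18 fell, camera adjusted p = 7.27e-10, and adjusted p = 0.0460 with an estimated correlation), collecting duct principal cells (9 of 9 fell, camera adjusted p = 7.27e-10, and 0.00282 with an estimated correlation) and intercalated cells (8 of 8 fell, camera adjusted p = 1.60e-08, and 0.0460 with an estimated correlation). Macrophage genes rose in 14 of 15 cases (camera adjusted p = 8.27e-08, and adjusted p = 0.162 with an estimated correlation) and endothelial genes fell in 11 of 14 (camera adjusted p = 6.62e-06, and adjusted p = 0.156 with an estimated correlation). The called lists were those called against control kidney, each in the same direction, except that the matrix list was not called here (9 rose and 1 fell of 22, camera adjusted p = 0.108), and the difference between the comparisons was not tested for it. Adjusted over the list alone, the counts were 14 up in DNA repair, 10 up and 2 down in hypoxia, 1 up and 17 down in xenobiotic metabolism, 1 up and 8 down in androgen-dependent genes, 15 up and 3 down in injury, 7 up and 4 down in apoptosis and 5 up in MHC class II. In the other lists they equalled the counts over all genes. The median and the test differed in sign for growth factor signalling, renal cancer tumour suppressors and fibroblasts, none of them called. The p53 call ended without the carcinoma arrays 3 and 5 (adjusted p = 0.0961) and with the 3' to 5' mean as a covariate (0.0833), which also ended the calls of MHC class II (0.0833) and Egr1 (0.0993). Egr1 lost its call with weights per array (0.0860) and with 1 weight per group (0.0583) as well. Without the carcinoma arrays 3 and 5 the calls of hypoxia (0.150), MHC class II (0.203), the unfolded protein response (0.117) and podocytes (0.104) ended too, and with the values as scaled by the authors that of the antioxidant list (0.0608, and 0.0705 on centred arrays).

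The third comparison asked how non-tumour kidney of exposed mice differed from control kidney. NRF2 targets lay higher as a group in treated kidney: 19 of 22 were above control, with a median of 0.46, Ephx1 at 1.58 ± 0.28 (adjusted p = 0.0707) and the glutathione transferase Gstp1 at 0.67 ± 0.11 (adjusted p = 0.0634). None of the 22 was called over all genes and 7 rose when adjusted over the list alone, and the list passed both tests (camera adjusted p = 7.28e-12, and adjusted p = 0.0131 with an estimated correlation). Without the carcinoma arrays 3 and 5 the second was not passed (adjusted p = 0.189) and 3 of the 22 were called over all genes, at the same median. Of 24 p53 target genes 18 were above control, with a median of 0.26, Cdkn1a at 1.66 ± 0.31 (adjusted p = 0.0786) and Trp53inp1 at 0.77 ± 0.18 (adjusted p = 0.361). Here 0 were called over all genes and 4 rose when adjusted over the list alone (camera adjusted p = 2.16e-06, and adjusted p = 0.0727 with an estimated correlation), and Mdm2 lay at 0.24 ± 0.11 (adjusted p = 1.00). The single gene called was Tmem43, an inner nuclear membrane protein, which rose by 0.90 ± 0.13 (adjusted p = 0.0247), from 8.47 ± 0.24 to 9.37 ± 0.24 (mean log2 signal, SD, n = 6).

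**Figure D4:**
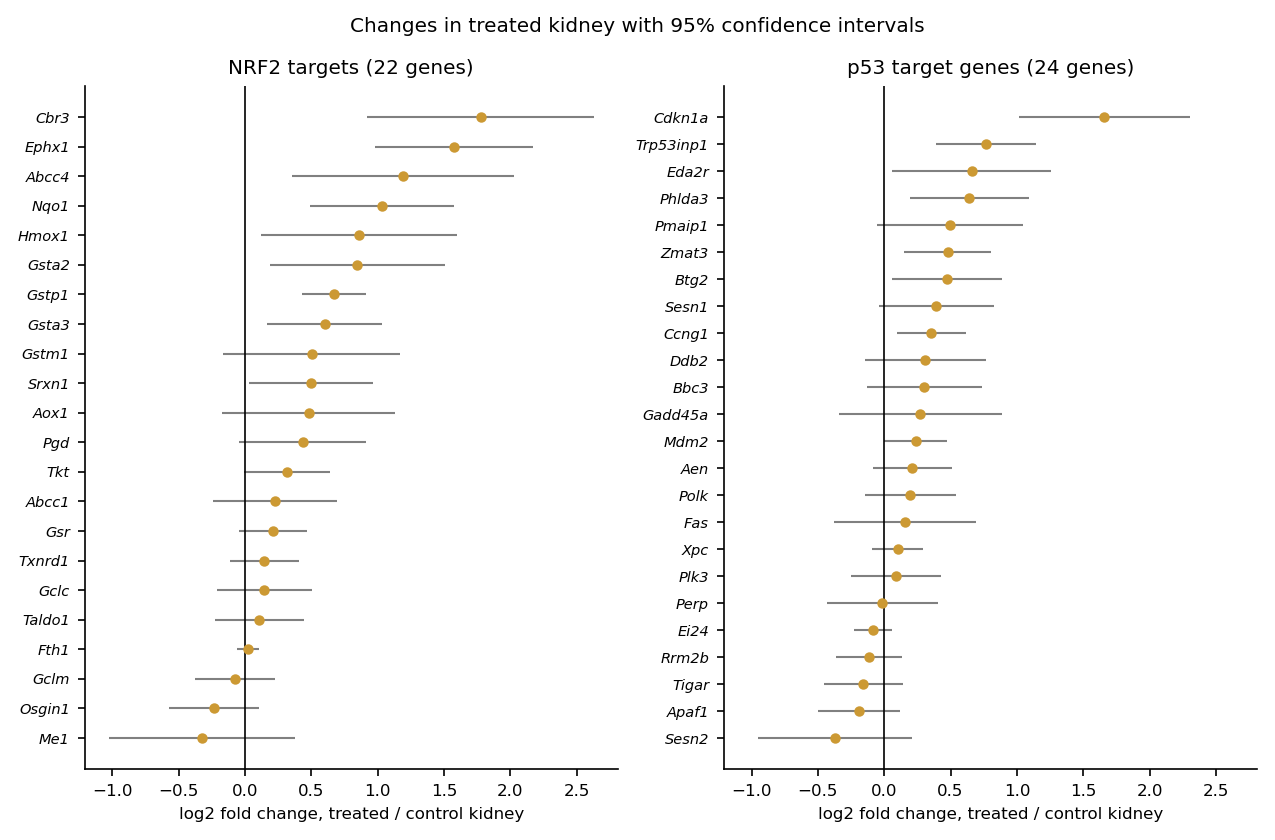
Log2 fold change of treated over control kidney with its 95% confidence interval for each gene of the NRF2 list (22 genes) and the p53 target list (24 genes). The points lie above 0 for 19 NRF2 targets and 18 p53 target genes.

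Limma called 1 gene at an adjusted p under 0.05 in treated against control kidney. An unadjusted p under 0.05 was found in 519 genes, 246 higher and 273 lower. Without any change 591 are expected if the 3 groups have the same spread. These p values used a spread shared with the carcinomas, so 519 against 591 cannot show that no gene changed. The groups did not overlap in 133 genes, where chance gives 0.216% of genes, or 25.6. The count depended on how the spread was modelled. It was 330 with weights per array, 23 with 1 weight per group and 7 in the 12 arrays alone. Without the control arrays 5 and 6 it stayed at 1, Tmem43, when the carcinomas were in the fit, and was 310 when they were not, with 7 NRF2 targets up and Me1 down, and 3 p53 target genes up. It fell to 0 without treated 1, 3 or 4 or without control 1, 2, 3, 4 or 6, where Tmem43 had an adjusted p of 0.0502 to 0.115, and rose to 12 without treated 5, to 3 without treated 6, to 6 without carcinoma 3 and to 2 without carcinoma 2 or control 5. In those 10 arrays the median was 0.54 for NRF2 targets (camera adjusted p = 9.93e-07, and adjusted p = 0.583 with an estimated correlation) and 0.22 for p53 target genes (camera adjusted p = 0.00595, and adjusted p = 0.672 with an estimated correlation).

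In treated kidney 14 of 15 macrophage genes were above control, with C1qb at 0.61 ± 0.23 and Ms4a7 at 0.47 ± 0.19 (both adjusted p = 1.00), and 0 were called (camera adjusted p = 0.000245, and adjusted p = 0.969 with an estimated correlation). Of 22 injury genes 18 were above control, with the lectin Lgals3 at 0.84 ± 0.25 (adjusted p = 0.752) and Krt20, dim in control kidney, at least 1.84-fold above it in the group means (adjusted p = 1.00), and 0 were called (camera adjusted p = 0.0141, and adjusted p = 0.969 with an estimated correlation). The injury call ended without treated 4 (adjusted p = 0.0902) or control 1 (0.0562), and the macrophage call without the control arrays 5 and 6 (0.0542). Among proliferation genes 18 of 24 were above control (camera adjusted p = 0.0508, and adjusted p = 0.969 with an estimated correlation), and camera called them with the replicate block (0.0438), on the authors' scaling (0.0272) and on centred arrays (0.0166). In oxidative phosphorylation 11 of 18 genes were below control, with a median of −0.01 (camera adjusted p = 0.892), and camera called the list on the authors' scaling (0.00113) and on centred arrays (0.00177). Calb1 lay at 0.80 ± 0.21 (adjusted p = 0.509) and Slc12a3 at 0.31 ± 0.28 (adjusted p = 1.00) in the distal convoluted tubule list (camera adjusted p = 0.0589), and Scnn1g, a sodium channel subunit gene, at 0.48 ± 0.22 (adjusted p = 1.00) in the collecting duct list (camera adjusted p = 0.0589). The receptor gene Met lay at −0.50 ± 0.12 (adjusted p = 0.341), Ccnd1 at 0.57 ± 0.21 (adjusted p = 1.00), the transporter gene Slc22a8 at −0.87 ± 0.22 (adjusted p = 0.471), Apoa2 at −1.09 ± 0.28 (adjusted p = 0.509) and the chaperone Hsph1 at −0.60 ± 0.17 (adjusted p = 0.703). Met (adjusted p from 0.000945 to 0.0366), Cdkn1a (0.000945 to 0.0387), Ephx1 (0.000206 to 0.0245) and Gstp1 (0.000945 to 0.0393) passed with weights per array, with 1 weight per group, without the carcinoma arrays 3 and 5 and in the 10 arrays without carcinomas and the control arrays 5 and 6. With weights per array Trp53inp1, Lgals3, Krt20, Calb1, Ccnd1, Slc22a8, Apoa2, Hsph1, Gpx4 and Sod1 passed as well, at adjusted p from 0.0122 to 0.0326, and in the 10 arrays Trp53inp1, Calb1, Slc12a3, Scnn1g and Gpx4, at 0.0331 to 0.0463. Antioxidant enzymes showed a median of −0.03, with Gpx4 at 0.18 ± 0.05 (adjusted p = 0.703) and Sod1 at −0.21 ± 0.06 (adjusted p = 0.786), and androgen-dependent genes a median of −0.14, with Slc7a13 at 1.49 ± 1.22 and Timd2 at 0.91 ± 0.68 (both adjusted p = 1.00). Of the 13 androgen-dependent genes 6 were above control. Without the control arrays 5 and 6 this was 0 of 13, Slc7a13 and Timd2 included, and the median was −0.47.

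Of the 40 lists 4 were called in this comparison, each higher in treated kidney, and the other 36 were not. On centred arrays 13 were called, 10 up and 3 down, among them oxidative phosphorylation (adjusted p = 0.00177), and the count was 7 without treated 1, 3 or 5 or without control 3, 5 or 6, and 9 without control 4. Adjusted over the list alone, 1 gene passed in each of the xenobiotic, distal convoluted tubule, growth factor, immediate early, early proximal tubule and hepatocyte lists and 2 in the antioxidant list. The median, the mean and the test differed in sign for 7 lists, none of them called: antioxidant enzymes, androgen-dependent genes, apoptosis, interferon, complement, the unfolded protein response and podocytes. Without the control arrays 5 and 6, camera also called the androgen-dependent list lower (adjusted p = 0.00115, and 0.874 with an estimated correlation) and the distal convoluted tubule (0.00527, and 0.171), collecting duct (0.00967, and 0.171) and intercalated cell (0.00226, and 0.272) lists higher, so none of the 4 passed with an estimated correlation.

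The changes in treated kidney and in carcinoma, each against the same 6 control arrays, correlated at r = 0.339 across 11813 genes, which are not independent replicates. Simulated unchanged groups that share their controls gave a mean r of 0.319 (−0.101 to 0.866). The covariance was 0.0799, against 0.0161 in the simulated groups, a difference of 0.0639. With the control arrays divided between the comparisons r was 0.245 on average (0.113 to 0.332) and the covariance 0.0648. Some control arrays carried high Xist, unlike any treated or carcinoma array. A division that puts such an array on each side leaves this difference in both comparisons. The correlation was not computed without these control arrays, so these values alone cannot show a change shared by treated kidney and carcinoma.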

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

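All tests of the control arrays 5 and 6, of the carcinoma arrays 3 and 5, of the treated kidneys without the control arrays 5 and 6, and of splits of 10 arrays were chosen after the results were seen.

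In the genes named in the report and the array quality values, each group of 6 arrays was searched for an array far from the others, by its gap to the nearest array as a fraction of the group's range, against the critical value of Dixon's test for 6 arrays. Of 322 groups 13 lay beyond it (4.04%), and chance marks about 1 in 20 groups. In carcinoma, the array 5 was the highest for Slc12a3 (0.878, log2 signal 6.38 against 4.67 to 4.88 on the other arrays, all 6 below the array median of 6.85, so the gap may be noise), Gclm (0.772, 12.85 against 11.87 to 12.09) and Mylpf (0.722, 9.59 against 7.09 to 7.79). Low arrays in carcinoma were the array 4 for Vgll3 (0.645, 8.87 against 11.09 to 12.31) and the array 3 for Ifi207 (0.631, 7.85 against 10.22 to 11.60). In treated kidney, the array 6 was low for Abca13 (0.664, 10.91 against 11.78 to 12.22) and high for Gstp1 (0.629, 14.42 against 13.56 to 13.88), and the array 5 was low for Ccl2 (0.662, 6.34 against 7.69 to 8.38). In control kidney, the array 4 was high for Mdm2 (0.756, 10.25 against 9.80 to 9.91) and low for Flt1 (0.635, 9.04 against 9.34 to 9.52). The control array 5 was high for Cdkn1c (0.651, 10.86 against 9.47 to 9.95), the control array 6 low for Hsph1 (0.690, 11.88 against 12.16 to 12.28) and the control array 1 low for Txnrd2 (0.629, 8.74 against 9.14 to 9.37).

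Signal also changed in probe sets outside the gene tests. Of 10092 probe sets without exactly 1 gene symbol, 3274 were bright enough to test, and limma called 792 of them higher in carcinoma than in control kidney and 562 lower. Against treated kidney the counts were 664 and 495, and in treated against control kidney 0 were called.

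The control arrays 5 and 6 carried high Xist, and the mean of their androgen-dependent genes lay below that of each other control array (log2 difference of −3.07 between the higher of the 2 and the lowest of the other 4), so a candidate explanation is that these 2 kidneys came from female mice. Female RNA mixed into male RNA is argued against by Eif2s3y, which was at 1.73% of its mean signal in the other 4 controls. A swap with a carcinoma array is argued against by their correlation across genes, higher with the mean of the other 4 controls than with the carcinoma mean by at least 0.144. A swap with a treated kidney cannot be told apart from these values, as 1 treated array, treated 5, lay nearer to the control arrays 1 to 4 (r = 0.987) than to the other 5 treated arrays (r = 0.979), and its NRF2 target mean of 0.12 lay between those of the control arrays 1 to 4 (−0.11 to −0.01) and of control 5 (0.25), with control 6 at 0.08 and the other 5 treated arrays at 0.41 to 0.76. On the third principal component treated 5 (15.25) and treated 6 (6.48) both lay toward the control arrays 1 to 4 (17.06 to 21.27). The other treated arrays lay at −19.47 to −6.22, near control 5 (−21.94) and control 6 (−21.62). The nearness of treated 5 is therefore not particular to a swap. A sample from outside the series stays open too, and the treatment protocol names both sexes although the title names male mice.

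The carcinoma arrays 3 and 5 lay nearer to kidney than the other 4, and kidney tissue in the piece as the whole cause is argued against by the nephron segments, which moved apart: the median change from control was −0.60 and −0.73 over 18 early proximal tubule genes and −3.69 and −3.44 over 28 genes of later segments, so the smaller difference was 2.71 (permutation of the genes for the mean of the 2 arrays, p = 0.00097, although genes are not independent replicates). Single genes did not all follow these medians. Slc34a1 of the proximal tubule lay at 11.31 and 9.08 against a control mean of 13.91, Umod at 12.05 and 11.44 against 14.67, and Aqp2 of the collecting duct at 6.23 and 6.92 against 10.18. Thus Slc34a1 fell about as far as Umod in carcinoma 3 and further than Umod in carcinoma 5. RNA degradation is argued against by the 3' to 5' mean, for which 2 of the 2 arrays lay within the range of the other 4 carcinomas. The S3 proximal list, of which the androgen-dependent list also holds 3 of 8 genes, had means of −3.30 and −2.38 against −1.48 and −1.61 for the early list, so the proximal tubule as a whole did not move as one. A share of early proximal tubule tissue and a less dedifferentiated tumour may both leave such values and stay open, and no biological explanation was tested.

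NRF2 targets lay higher as a group in treated kidney. Female control arrays as the whole cause are argued against by the fit without the control arrays 5 and 6 (p = 0.000729 with an estimated correlation, 19 of 22 genes higher, median 0.54), RNA degradation by the fit with the 3' to 5' covariate (p = 0.000945, 19 of 22 genes higher, median 0.33 against 0.46 before, so it took up part of the change), and the normalization by the fits on the authors' scaling and on centred arrays, with p = 0.000535 as the larger of the 2. The adjusted p lay between 0.00295 and 0.0378 in these fits and with each treated or control array left out, but was 0.189 without the carcinoma arrays 3 and 5, where the median change stayed at 0.46, and 0.583 in the 10 arrays of treated and control kidney without the control arrays 5 and 6, where the median was 0.54, 7 of the 22 genes were called higher and camera gave an adjusted p of 9.93e-07. An exposure effect on these genes may explain the rise, as a hypothesis found and tested on the same arrays. RNA degradation, the dose of the treated mice and a swap of treated with control arrays stay open. Each treated sample is also titled hyperplasia, so exposure and hyperplasia of the sampled kidney cannot be told apart here.

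Splits of the arrays without regard to their group were tested with 100 drawn at a fixed seed, the real split included. Chance was excluded for the genes called in carcinoma against control kidney (1 of 100 splits as large, real 6069, highest other 4053) and against treated kidney (1 of 100, real 5719, highest other 3696). As many lists as in the real split were called in 2 of 100 splits against control kidney (real 25, highest other 27). Against treated kidney this was also 2 of 100 (real 24, highest other 25). A split that mixed the groups called more lists in each case, so the count of lists does not exclude chance. The NRF2 targets in treated kidney reached their value in 1 of 100 splits, the real one (mean moderated t real 1.96, highest other 1.61). That list was picked from those tested on these same arrays, so its split test does not exclude chance either. For the genes called in treated against control kidney, 2 of 100 splits called as many (real 1, highest other 52), but a count of 1 gene is too small for this to exclude chance: 98 splits called 0, and the call was lost without 8 of the 12 arrays in turn. The split with 52 genes set treated 1 to 4 with the control arrays 5 and 6 against the rest. The 2 sides also lay apart on the third principal component (4.16% of the variance), at −21.94 to −6.22 against 6.48 to 21.27. The Gapdh 3' to 5' difference parted them too, at −0.487 to −0.396 against −0.578 to −0.529. So a structure of the samples other than their group runs across the treated and control arrays. It cannot be fully told apart from the group when treated and control kidney are compared, and its source was not tested. That split also kept treated 1 to 4 apart from control 1 to 4, so its count may follow the group in part. In the 10 arrays without the control arrays 5 and 6, 2 of 100 splits called as many genes (real 310, highest other 424). A split other than the real one called more, and this setting was chosen after the results were seen, so chance was not excluded. The split with 424 genes set treated 2 and 5 with control 1 to 4 against treated 1, 3, 4 and 6, so it followed the group in part. For the lists called in treated against control kidney chance was not excluded (86 of 100, real 4, highest other 17).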

How the results depend on the processing

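The values on the authors' scaling, without the control arrays 5 and 6 or the carcinoma arrays 3 and 5, with 1 weight per group and in the 10 arrays, and the lists on centred arrays or with each array left out, were tests chosen after the data were seen. Of the settings run for a count, those without a value here kept it within 1.5 times that of the report.

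Genes called in carcinoma against control kidney lay between 4184 (stricter filter on dim probe sets) and 7700 (without the carcinoma arrays 3 and 5), and against treated kidney between 3935 and 7406, apart from 2140 and 1924 with a 2-fold minimum, which asks for a larger change. With each array left out the ranges were 5558 to 6794 and 5168 to 6541. In treated against control kidney limma called 1 gene. The count was 0 on centred arrays, with the 3' to 5' covariate, with the replicate block and with the 2-fold minimum, 4 with the stricter filter (fewer genes tested), 7 in the 12 arrays alone, 13 without the carcinoma arrays 3 and 5, 23 with 1 weight per group, 330 with weights per array, 310 in the 10 arrays, and 0 to 12 with each array left out. Apart from the settings noted, the cause was not tested. Correlations between arrays of the same replicate number lay between −0.310 and 0.139. Such values cannot decide whether the numbers pair mice, as samples of 1 mouse need not vary together.

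With an estimated correlation 1, 3 and 1 lists were called in carcinoma against control, carcinoma against treated and treated against control kidney, and the cause was not tested. The 4 lists called in treated kidney became 1 with fry, 7 with the covariate, 9 on the authors' scaling (6 up and 3 down), 13 on centred arrays (10 up and 3 down), 4 to 9 with each array left out and 7 without the control arrays 5 and 6 (6 up and 1 down), and the cause was not tested. With the controls divided between the comparisons, the correlation of treated and carcinoma changes was 0.245. Arrays were then no longer shared and each comparison had 3 control arrays, and the effects of these changes cannot be told apart. Control arrays with high Xist could still fall on both sides of the division.

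Among the named genes, 1 reversed: Mdm2 in carcinoma against control kidney, at −0.00879 (adjusted p = 0.964) with the most variable probe set, a different probe set of the gene. Of the other values for named genes, in carcinoma against control kidney 1832 kept their direction and side of the threshold, 5 passed it and 21 fell short. The counts were 595, 0 and 3 against treated kidney and 334, 35 and 3 in treated against control kidney. For lists they were 311, 14 and 35, then 317, 13 and 30, then 330, 23 and 7. The alternatives set for Trp53 were not run, as no probe set, with 1 symbol or several, is annotated to it. Of 5301 genes with several kept probe sets, 69 had probe sets called in opposite directions in carcinoma against control kidney. The count was 29 against treated kidney and 0 in treated against control kidney. For such genes the direction given rests on the probe set chosen. Signal near the array median limited the folds of dim genes to a lower bound.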

Other observations

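The test of the Y-linked genes in carcinoma 2, carcinoma 5 and treated kidney 4 was chosen only after the result was seen, and those of the serine and lysosome lists were written before their values were seen.

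The rise of Aldh1l2, Asns and Trib3 in the carcinomas led to a wider list of serine, one-carbon and amino acid uptake genes, of which 13 of 14 were measured. In carcinoma against control kidney 6 rose and 3 fell, with a median of 0.80 (camera adjusted p = 0.382, and adjusted p = 0.573 with an estimated correlation), so a broader rise was not shown and stays undecided. The proline synthesis enzyme Aldh18a1 rose by 2.93 ± 0.38, the mitochondrial folate enzyme Mthfd2 by 1.74 ± 0.24 and the serine synthesis enzyme Psat1 by 1.69 ± 0.50. The cytosolic folate enzyme Mthfd1 fell by 2.22 ± 0.14, Shmt1 fell by 1.39 ± 0.20 and Shmt2 fell by 1.14 ± 0.29. A candidate explanation is a rise of single enzymes of this group without the rest, which these tests leave open.

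The rise of Gpnmb and Cd68 led to a list of lysosomal genes, of which 25 of 29 were measured. In carcinoma against control kidney 16 rose and 1 fell, with a median of 0.55 (camera adjusted p = 5.17e-05, and adjusted p = 0.0677 with an estimated correlation), so a broader rise stays undecided. The galactosidase Gla rose by 3.00 ± 0.47, the cholesterol transporter Npc1 by 1.17 ± 0.23, the ceramidase Asah1 by 1.11 ± 0.07 and the cathepsins Ctsb by 1.04 ± 0.11 and Ctsd by 0.94 ± 0.08. The proton pump subunit Atp6v1a fell by 0.55 ± 0.08. Macrophages in the tumours may bring these transcripts, since 14 of 15 macrophage markers rose too, and tumour cells were not told from them here.

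In carcinoma 2, carcinoma 5 and treated kidney 4 the Y-linked genes lay below the other arrays of their groups with low Xist. Eif2s3y was at 17.6%, 44.0% and 32.8% of the signal of the other arrays, Uty at 23.8%, 45.4% and 29.0% and Kdm5d at 16.1% and 41.9% in the last 2, its signal in carcinoma 2 being below the array median. Female RNA in these samples is argued against by Xist, whose highest signal there was 99.3 where at least 7395 was needed. Loss of the Y chromosome in part of the cells may explain the values and was not tested further.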
